A study of Arabidopsis thaliana with 6 samples.

How the data were processed

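Total RNA of 10-day-old Arabidopsis seedlings was sequenced in 6 libraries, 3 of the Columbia wild type and 3 of the hb34 mutant, with paired-end Illumina reads per the labels' protocols. The authors deposited raw counts per gene, 1 table per library, which were used as deposited. HISAT2 2.1.0, DESeq2 1.30.1 and the build TAIR10 are named in the submitters' processing notes, without their roles. Per the file headers, each count is over the exons of a gene. The counting program, its strand setting and its treatment of reads with several matches are not given in the sources used here, so values of near-identical copies (CYP79F1 and CYP79F2, LHCB2.1 and LHCB2.2, CYP79B2 and CYP79B3, the AOC and PDF1 genes), of overlapping genes and of antisense genes are uncertain. The values were whole numbers, and the library totals ran from 17562497 to 19670468.

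Gene identifiers and coordinates in the files were compared with the RefSeq annotation of TAIR10.1. The exons of 38187 of 38189 genes lay inside the same gene of that annotation, and 0 genes reached beyond the end of a sequence. Coordinates are those of that build, counted from 1. Gene symbols come from the lists fixed in advance or from RefSeq; a gene with no symbol, or with one that another gene carries, is named by its locus.

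Groups come from the sample titles. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (glmQLFit with legacy FALSE, glmQLFTest, genotype as the only term), with Benjamini-Hochberg adjustment over 17905 genes and a threshold of 0.05. The tested genes held at least 99.891% of each library's counts. CPM are on TMM-scaled library sizes, log2 CPM have a prior count of 2, and the standard error of a log2 fold change is the size of the unshrunk coefficient divided by the square root of F. All tests are two-sided unless stated. A fold against a group without a read was computed against 3 counts over the group; such floors cover counting error only.

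Gene lists were tested with limma 3.58.1 camera on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over 25 lists with at least 2 measured members, and again with the correlation estimated and with fry. The 27 lists hold 379 members, all found in the files. They were fixed before the data were examined: the zinc finger homeodomain family, 5 jasmonate lists (synthesis, signalling, catabolism, responsive genes of the MYC and of the ERF branch), salicylate, pattern-triggered immunity, camalexin, aliphatic and indolic glucosinolates, touch and wound, abscisate and drought, heat shock, clock, photosynthesis, auxin, cell wall expansion, brassinosteroid and gibberellin, cell cycle, flavonoids, phosphate, iron, senescence, root markers, seed storage markers and reference genes. CYP79B2 and CYP79B3 were placed in the camalexin list. None of the lists was chosen on these samples.

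The genes named follow a rule fixed at the same time. It takes HB34, then, among genes past the threshold whose groups do not overlap and whose mean log2 CPM is at least 1, the 8 largest rises, the 8 largest falls and the 6 smallest p. From each list it takes the members with the smallest p, up to 4 for the jasmonate, salicylate and immunity lists and up to 2 for the others. The following were chosen after their values were seen: list members named because they belong to a count (SOT16, MAM1, CYP79F2, FMOGS-OX1, EXPA5, XTH19, LHCB3, PETE2 and BTS), the chromosome 2 segment, AT1G10690, AT1G10710, the clock genes of the time-of-day test, and the gene families grouped by RefSeq product. The loci related to PRS3 were chosen after the values of PRS3, but not their own, were seen. AOC4 was named outside the rule, as a jasmonate synthesis gene that lay lower in hb34.

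The end of the chromosome 2 segment is the single change point that best divides the log2 fold changes of 2355 genes on that chromosome with a mean log2 CPM of at least 1. Windows of 1 Mb were compared with the other tested genes by Fisher's exact test, as were genes within 1 Mb of HB34. The replicate numbers were tried as a block, as the closing section describes. The fit was tested on simulated counts for hb34 against WT with 200 changed genes: of 17599 genes tested there, it called 3.03% of those changed 1.5-fold, 29.85% of those changed 2-fold and 86.15% of those changed 4-fold in the right direction, and 6 of 17401 unchanged genes. With only 200 changed genes the simulation has a stricter p cutoff than the data, where 5321 genes had an unadjusted p under 0.05. These shares therefore do not carry over to the data, though small changes may still be missed.

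The alternatives set before the data were examined were DESeq2 size factors, upper quartile scaling and library size only; no filter beyond a total above 0, and a CPM of at least 1 in 3 libraries; DESeq2 1.42.0 and limma-voom; legacy and robust dispersions; nuclear genes only; a replicate block; an adjusted p under 0.01; a fold change of at least 2; leaving out each library; other list tests; and windows of 0.25 and 5 Mb around HB34. Added after the data were examined were the removal of the chromosome 2 segment from the genes and the lists, the homeodomain family without HB34 and the test of gene families. Adjusted p that DESeq2 gave as missing stayed missing. DESeq2 was run without the count filter and left some genes without a p, so its counts rest on other numbers of genes. They were 342 in the chromosome 2 segment (250 with edgeR) and 21 in the salicylate list (16 with edgeR). They were 16 in the jasmonate synthesis list (19 with edgeR), and 7 and 9 in the catabolism and ERF branch lists (8 and 7 with edgeR). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.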

Results

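Gene expression was measured by RNA sequencing in material from 10-day-old Arabidopsis thaliana seedlings. It came from the Columbia wild type (WT, n = 3) and the hb34 mutant (n = 3). Plants grew with 16 h of light and 8 h of dark at 22 °C. HB34 encodes a zinc finger homeodomain transcription factor, and the series title places it between jasmonic acid synthesis, immunity and growth. The labels call the material leaves, while the extraction protocol names seedlings. Of 16 root markers 1 had enough counts to be tested, which argues against whole seedlings with roots. The libraries held 18407184, 17562497 and 19537297 counts in WT replicates 1 to 3 and 18240122, 19670468 and 18950623 in hb34 replicates 1 to 3. Of 38189 genes in the files, 17905 had enough counts to be tested, and a floor of 3 counts corresponded to 0.153 to 0.178 CPM, the count scaled to a common library size, in a library. Nothing in the labels says whether replicates came from separate plant pools, so the p-values measure the spread between these samples.

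HB34 transcript was nearly absent from the mutant. HB34 (AT3G28920, chromosome 3, 10940305 to 10941833, minus strand, a protein-coding gene) had 1571, 1547 and 1821 counts in the WT libraries and 19, 43 and 23 in the hb34 libraries. Its mean level was 89.4 ± 5.3 CPM (SD, n = 3) in WT and 1.49 ± 0.68 CPM (SD, n = 3) in hb34, which is 1.67% of the WT mean. The log2 fold change, hb34 minus WT throughout, was -5.90 (SE 0.254, edgeR adjusted p = 0.000419). What kind of allele the mutant carries is not given in the sources used here. Of the 12 measured members of the zinc finger homeodomain family, HB34 included, HB25 also fell (log2 fold change -0.63, SE 0.145, adjusted p = 0.0473), and the other 10 did not pass the test. The HB25 call was kept in 9 of 18 alternatives and lost without each library in turn except hb34 replicate 2. When adjusted over the list alone 2 of the 12 fell. As a list the family was lower (median -0.43, camera adjusted p = 0.0328; adjusted p = 0.598 with an estimated correlation), but without HB34 itself, an alternative chosen after seeing the data, its adjusted p was 0.13. Without a filter on low counts that of the full list was 0.0562.

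In all, 675 genes were higher and 447 lower in hb34 at an adjusted p under 0.05 (edgeR quasi-likelihood test, 1122 of 17905), of which 334 and 160 changed at least 2-fold. With upper quartile scaling the split was 536 higher and 615 lower. CPM of all 3 hb34 libraries lay above or below all 3 WT libraries for 35.3% of tested genes, against the 10% that chance gives for 3 against 3. The number of calls depended on single libraries: 3 genes passed without WT replicate 1, 4 without WT replicate 2 and 389 without hb34 replicate 3. At an unadjusted p under 0.05 these fits had 3347, 3488 and 5339 genes, against 5321 with all libraries. The calls thus fell far more than the small p-values did. Of 54 genes named by the rule or in a count that passed, 3 kept the call without WT replicate 1, 4 without WT replicate 2, 32 without WT replicate 3, 44 without hb34 replicate 1, 50 without hb34 replicate 2 and 32 without hb34 replicate 3. HB34, AT1G14580 and AT1G75945 kept theirs without each of the 6 libraries in turn.

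A run of genes at the start of chromosome 2 was higher in all 3 hb34 libraries. From the first tested gene to the end of AT2G05540 at position 2034283, an end point estimated from the data, 154 of 250 tested genes rose and 0 fell, with 205 higher and 0 lower at an unadjusted p under 0.05 in edgeR. DESeq2 called 185 higher and 0 lower of 342 genes there, and limma-voom 147 and 0 of 250. Among the 218 of these genes with a mean log2 CPM of at least 1, the median log2 fold change was 0.95, and 194 had all hb34 libraries above all WT libraries (chance separates 10% of genes in either direction). The medians were 0.954, 0.896 and 0.977 in hb34 replicates 1, 2 and 3. At the same expression level the median over the rest of the genome was 0.0057. The segment holds the DELLA growth repressor gene RGA (log2 fold change 0.80, SE 0.096, adjusted p = 0.012), the light-harvesting genes LHCB2.1 and LHCB2.2, AT2G01180, AT2G03140 and RNEE/G, whose product is an RNase E/G-like endonuclease. Outside it, 521 genes rose and 447 fell. With its genes taken out before filtering and scaling, chosen after seeing the data, 382 genes rose and 327 fell.

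**Figure D1:**
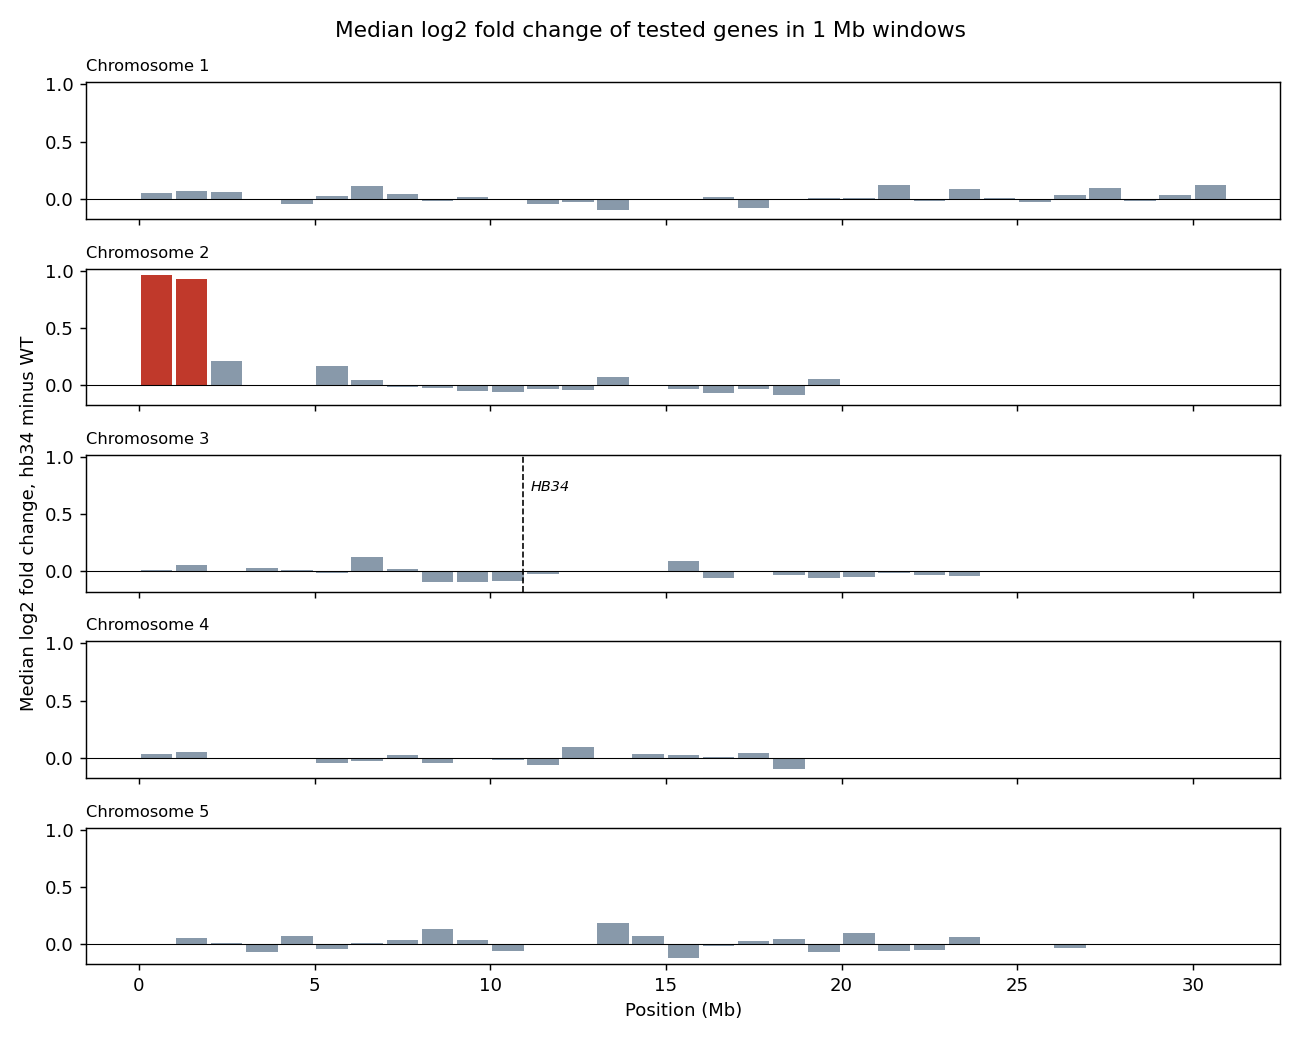
Median log2 fold change (hb34 minus WT, vertical axis) of tested genes in 1 Mb windows with at least 20 tested genes along chromosomes 1 to 5 (position in Mb, horizontal axis); red bars mark windows with more changed genes than the rest of the genome (Fisher's exact test, adjusted p under 0.05), and the dashed line marks HB34. The first 2 windows of chromosome 2 had medians of 0.964 and 0.924, and the medians of the other windows shown, apart from the third of chromosome 2, lay between -0.122 and 0.181.

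Among the genes that met the rule for naming, the largest changes included that of PRS3 (AT1G10700, chromosome 1, 3554104 to 3556544), a phosphoribosyl pyrophosphate synthase gene. PRS3 had 522, 480 and 439 counts in WT and 0 in each hb34 library, so it was at least 498-fold lower (against a floor of 3 counts over the 3 hb34 libraries together, counting error only; adjusted p = 0.00222). AT1G14580 fell from 21.2 ± 1.25 to 3.41 ± 0.545 CPM (SD, n = 3 each). The other large falls were those of PR1, the lipase gene AT5G45670 (log2 fold change -4.07), the pathogen- and clock-controlled gene PCC1 (-2.88), AT5G02890 (-2.73), the asparagine synthetase gene ASN1 (-2.67) and the expansin gene EXPB1 (-2.56). ELIP2, an early light-inducible gene, fell from 12.9 ± 1.5 to 3.12 ± 0.301 CPM (SD, n = 3 each). AT1G75945 had the largest rise among them, from 0.205 ± 0.133 to 10.6 ± 1.2 CPM (SD, n = 3 each; log2 fold change 5.68, SE 0.328, adjusted p = 0.00111). Next came the glucosyltransferase gene UGT73C1 (3.57), AT1G50745 (3.53), AT3G29639 (3.52), MLO12 (3.48), AT2G01180 (3.42), IGMT1 (3.32) and AT1G69790 (3.27). Of these 7 genes all but UGT73C1 were highest in hb34 replicate 2. Without that library the log2 fold changes of AT2G01180, AT1G69790, MLO12 and IGMT1 were 2.06, 2.21, 2.77 and 2.64, and all 4 still passed. None of the 4 passed with limma-voom, or without WT replicate 1, 2 or 3 in turn, and AT2G01180 and AT1G69790 also failed with robust dispersions. Without WT replicate 3 the log2 fold change of ASN1 was -2.07, and without WT replicate 2 that of AT1G75945 was 6.28.

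Of 19 measured jasmonate synthesis genes, 16 had a positive log2 fold change and 3 a negative one. With edgeR 0 of 19 passed (10 at an unadjusted p under 0.05, 9 of them higher), and 0 passed when adjusted over the list alone. DESeq2, which gave a p to 16 members of the list, called 3 higher, and limma-voom called 0. LOX2, which encodes a lipoxygenase of the first step, had 86.6, 94.0 and 155.1 CPM in WT and 203.2, 477.7 and 208.1 CPM in hb34 (log2 fold change 1.41, SE 0.378, adjusted p = 0.0657). LOX4 had 9.35 to 10.6 CPM in WT and 19.5, 508.3 and 49.1 CPM in hb34 replicates 1, 2 and 3 (4.26, SE 1.16, adjusted p = 0.0672). LOX3 (3.08, SE 0.963) and OPCL1, a CoA ligase gene of the pathway (2.60, SE 0.755), were likewise highest in hb34 replicate 2 and next highest in hb34 replicate 3. AOC4, an allene oxide cyclase gene, lay lower in all 3 hb34 libraries (22.5 ± 3.17 CPM in WT, 15.6 ± 2.27 CPM in hb34, SD, n = 3 each; adjusted p = 0.0913). Without hb34 replicate 2, 4 of the 19 passed: LOX4 (log2 fold change 1.78), OPCL1 (1.11), LOX3 (0.89) and LOX2 (0.88), with adjusted p between 0.0131 and 0.048. Without hb34 replicate 1, 2 passed, LOX4 and OPCL1. As a list, jasmonate synthesis was higher (median 0.71, camera adjusted p = 0.0361; adjusted p = 0.598 with an estimated correlation), and its medians were 0.181, 1.28 and 0.362 in hb34 replicates 1, 2 and 3. The list's adjusted p was 0.1 without WT replicate 2 and 0.0524 without WT replicate 3, and 0.0562 without a filter on low counts. With fry it was 0.203.

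The other 4 jasmonate lists were not past the threshold. Of 19 signalling genes 0 passed with edgeR (6 at an unadjusted p under 0.05), and 0 when adjusted over the list alone. DESeq2 called 2 of the 18 to which it gave a p, and limma-voom 0. The repressor gene JAZ1 had 11.4, 223 and 45.3 CPM in hb34 and 9.84 ± 3.42 CPM (SD, n = 3) in WT (adjusted p = 0.0819). JAZ9 (0.95), JAZ5 (2.49) and NINJA (0.33) had adjusted p of 0.103, 0.125 and 0.142. Without hb34 replicate 2 the log2 fold changes of JAZ1 and JAZ5 were 1.52 and 0.55. Of 8 catabolism genes 0 passed with edgeR (1 at an unadjusted p under 0.05; DESeq2 and limma-voom 0), and 0 when adjusted over the list alone. In that list CYP94B3, whose product hydroxylates jasmonoyl-isoleucine, had 0.429, 38.5 and 2.31 CPM in hb34, and the log2 fold changes of CYP94C1 and JOX2, positive with all libraries, were -0.92 and -0.22 without hb34 replicate 2. Of 9 responsive genes of the MYC branch 1 rose (3 when adjusted over the list alone). It was CORI3, a coronatine-induced lyase gene, which went from 35.0 ± 3.73 to 91.8 ± 10.7 CPM (SD, n = 3 each; log2 fold change 1.39, SE 0.138, adjusted p = 0.00833). JR1 had a log2 fold change of 0.63 and ANAC055 one of 4.37, with adjusted p of 0.0598 and 0.0915. ANAC055 had 1.02, 16.8 and 1.75 CPM in hb34, and its log2 fold change was 2.15 without hb34 replicate 2. Of 7 responsive genes of the ERF branch 0 passed with edgeR (3 at an unadjusted p under 0.05; DESeq2 called 1, limma-voom 0), and when adjusted over the list alone 1 rose and 1 fell. The defensin genes PDF1.3, PDF1.2B and PDF1.2A had 77.9, 46.9 and 46.9 CPM in hb34 replicate 2 and at most 13 CPM in any other library. Camera adjusted p were 0.125 for signalling, 0.356 for catabolism, 0.0681 for the MYC branch and 0.356 for the ERF branch. With camera's preset correlation the signalling list passed without WT replicate 1 (adjusted p = 0.0455) and without hb34 replicate 1 (adjusted p = 0.0157, with 2 genes that rose). The MYC branch list passed without WT replicate 1 (0.0341), without hb34 replicate 1 (0.0185), without hb34 replicate 3 (0.0311), with upper quartile scaling (0.0255) and with a replicate block (0.0465). With all libraries both lists had an adjusted p = 0.598 with an estimated correlation. On the first principal component of log2 CPM (55.5% of the variance) hb34 replicate 2 lay at 82.1, hb34 replicates 1 and 3 at 8.5 and 18, and the WT libraries between -41.2 and -25.8.

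**Figure D2:**
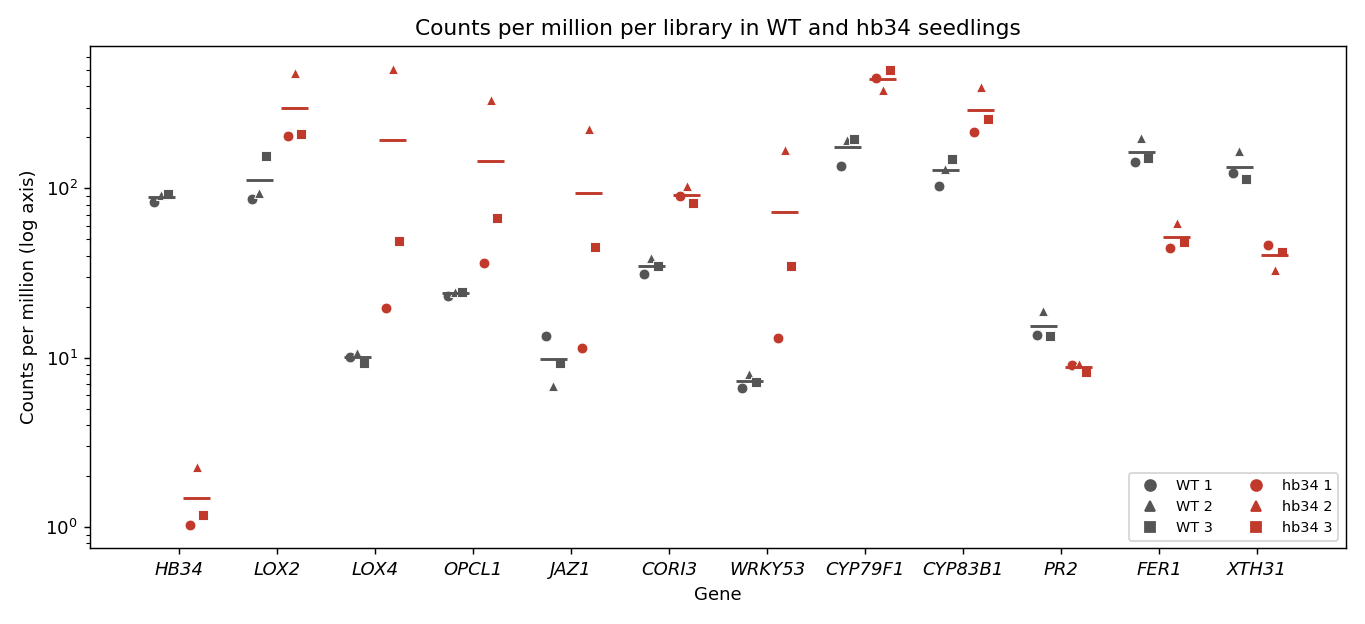
CPM (vertical log axis) of 12 genes in each library; gray symbols are WT, red symbols are hb34, circles, triangles and squares are replicates 1, 2 and 3, and horizontal lines are group means of 3 libraries. LOX4, OPCL1, JAZ1 and WRKY53 were highest in hb34 replicate 2, with 508.3 CPM for LOX4, while CORI3 lay between 82.4 and 103.5 CPM in the 3 hb34 libraries.

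Among defense genes 1 of the immunity list rose and 2 of the salicylate list fell. Of 16 pattern-triggered immunity genes 1 rose with edgeR (5 when adjusted over the list alone). DESeq2, which gave a p to 19 members of the list, called 5 higher, and limma-voom called 0. With edgeR it was CYP81F2, which encodes a hydroxylase of indolic glucosinolates. CYP81F2 had 2.38 ± 0.841 CPM in WT and 17 ± 14.2 CPM in hb34 (SD, n = 3 each, log2 fold change 2.83, SE 0.652, adjusted p = 0.0476). Its call was kept in 10 of 18 alternatives and lost with limma-voom, with robust dispersions and without each WT library in turn. WRKY53 (3.32), WRKY33 (2.16) and WRKY40 (3.14), transcription factor genes of the defense response, had adjusted p of 0.0628, 0.0728 and 0.0743 and were highest in hb34 replicate 2. Without that library the log2 fold changes of CYP81F2, WRKY53, WRKY33 and WRKY40 were 1.90, 1.73, 1.45 and 2.21, and CYP81F2 and WRKY53 passed. The list was higher (median 0.88, camera adjusted p = 0.02; adjusted p = 0.598 with an estimated correlation), with medians of 0.0965, 1.75 and 0.523 in hb34 replicates 1, 2 and 3, and without hb34 replicate 2 its median was 0.33. Without hb34 replicate 1, 4 of its genes rose, and without a filter on low counts its adjusted p was 0.0616. With fry the adjusted p of the immunity list was 0.203. In the salicylate list 2 of 16 genes fell and 0 rose with edgeR (2 higher at an unadjusted p under 0.05; DESeq2 called 1 higher, limma-voom 0), and when adjusted over the list alone 3 fell and 1 rose. PR1, the classical salicylate marker, had 218, 54 and 52 counts in WT and 1, 3 and 0 in hb34 (log2 fold change -6.25, SE 1, adjusted p = 0.0125), and PR2, a glucanase gene, had 15.3 ± 3.06 CPM in WT and 8.83 ± 0.524 CPM in hb34 (SD, n = 3 each; adjusted p = 0.0463). The log2 fold change of PR1 was -5.24 without WT replicate 1 (adjusted p = 0.054) and -7.47 without hb34 replicate 2. The PR1 call was also lost without WT replicate 2 and without hb34 replicate 3. That of PR2 was kept in 10 of 18 alternatives and lost with limma-voom and without each WT library in turn. CBP60G (1.56) and SARD4 (-0.46) had adjusted p of 0.0653 and 0.0796, and CBP60G had 0.94 without hb34 replicate 2 (adjusted p = 0.0369). The salicylate list had a median of 0.062, a mean of -0.18 and a camera direction of lower with an adjusted p of 0.648.

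Some glucosinolate synthesis genes rose in hb34. Of 18 aliphatic glucosinolate genes 5 rose, 14 when adjusted over the list alone, and 0 fell with edgeR, DESeq2 or limma-voom (0 lower at an unadjusted p under 0.05). CYP79F1, which encodes the entry enzyme acting on chain-elongated methionine, went from 175.2 ± 34.0 to 442.0 ± 58.3 CPM (SD, n = 3 each; log2 fold change 1.34, SE 0.173, adjusted p = 0.0125). MAM1 of the chain elongation step had 418.4, 323.8 and 469.3 CPM in the hb34 libraries and at most 189.9 CPM in WT, and CYP79F2 (1.25), FMOGS-OX1 (1.09) and SUR1 (0.92) were the other 3. The list was higher (median 0.74, camera adjusted p = 2.03e-07). Its adjusted p was 0.598 with an estimated correlation, which was 0.658, and 0.113 with fry. Many lists share this 0.598 through the adjustment, while their unadjusted camera p differed. With an estimated correlation these were 0.0423 for the homeodomain family, 0.0912 for indolic and 0.148 for aliphatic glucosinolates. They were 0.289 for jasmonate synthesis and 0.371 for the MYC branch. The medians of the aliphatic list were 0.871, 0.354 and 0.962 in hb34 replicates 1, 2 and 3, so here hb34 replicate 2 was the lowest of the hb34 libraries. Its count of genes that rose was 0 without WT replicate 1, 0 without WT replicate 2 and 14 without hb34 replicate 2. Of the 10 splits of the 6 libraries into 3 and 3, 7, the real one included, gave at least 6 lists past the threshold with camera's preset correlation. The preset-correlation p of this and the other lists therefore does not tell genotype from other groupings. Of 7 indolic glucosinolate genes 4 rose with edgeR (5 when adjusted over the list alone), 5 with DESeq2 and 2 with limma-voom. The 4 were IGMT1, CYP83B1 (127.5 ± 23.5 to 289.8 ± 96.2 CPM, SD, n = 3 each), SOT16 and UGT74B1. None of these passed without WT replicate 1 or without WT replicate 2, and SOT16 kept its call in 8 of 18 alternatives. The indolic list had a median of 0.92 and a camera adjusted p of 0.0361, with adjusted p = 0.598 with an estimated correlation. Its camera adjusted p was 0.0546 without WT replicate 2, 0.0805 without WT replicate 3 and 0.0621 with limma-voom. With fry its adjusted p was 0.113. Camalexin and indolic glucosinolates share the intermediate indole-3-acetaldoxime. In the camalexin list 2 of 5 genes rose (3 rose and 1 fell when adjusted over the list alone), CYP79B2 (log2 fold change 1.51, SE 0.252) and CYP79B3 (1.49, SE 0.245). Both belong to the step that makes this shared intermediate, and the other 3 genes did not pass. The list's camera adjusted p was 0.13.

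**Figure D3:**
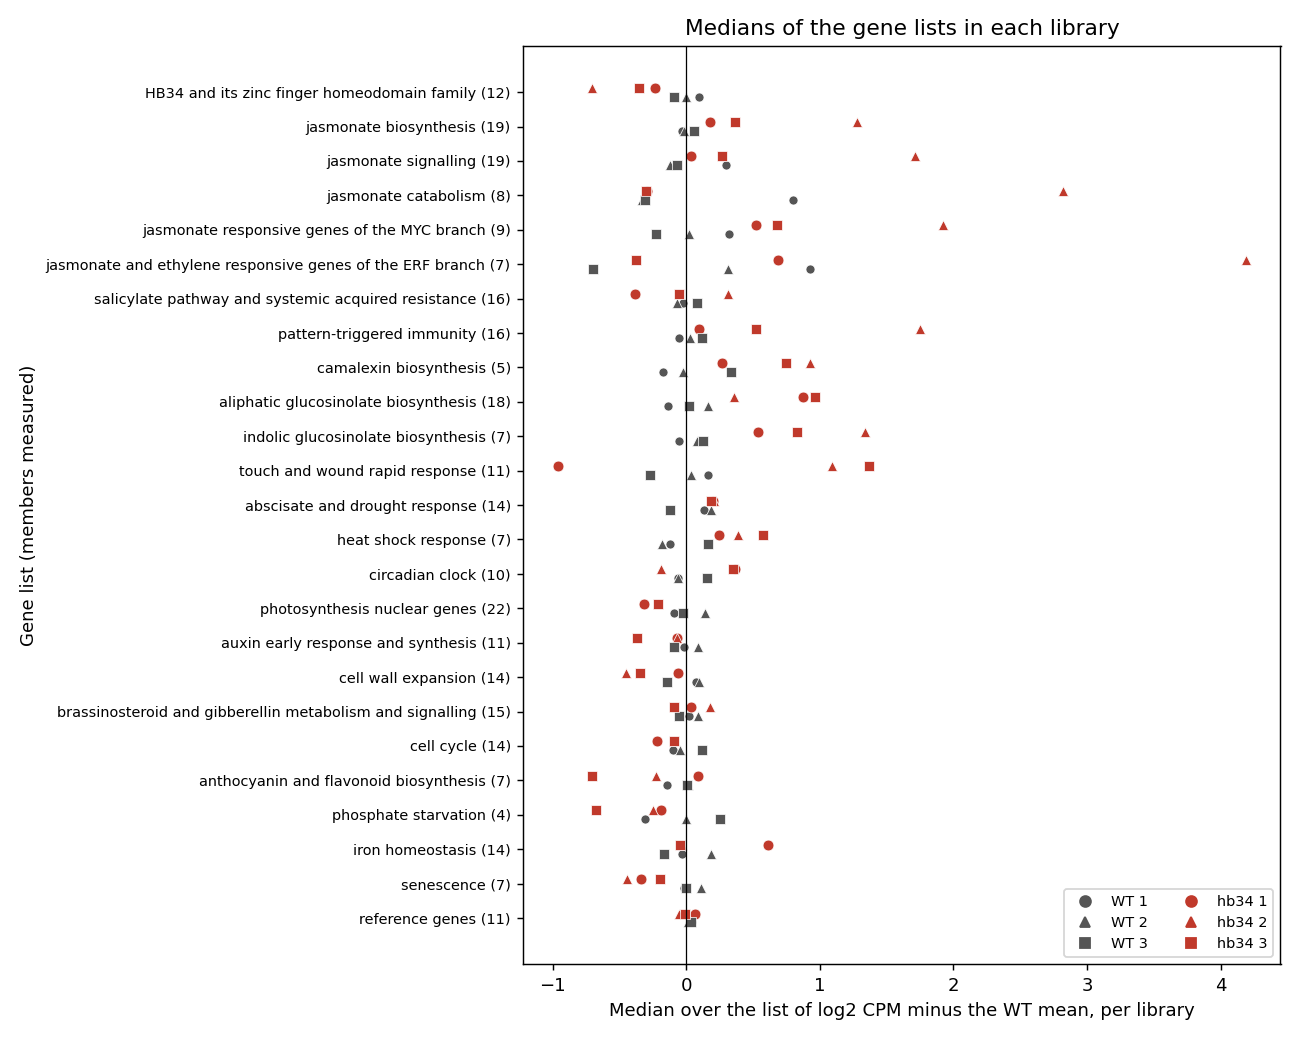
Median over each gene list of the log2 CPM minus the gene's WT mean (horizontal axis) in each library, with the number of measured members in parentheses; gray symbols are WT, red symbols are hb34, and circles, triangles and squares are replicates 1, 2 and 3. The 5 jasmonate lists and pattern-triggered immunity were highest in hb34 replicate 2, at 1.28 to 4.19, while aliphatic glucosinolate medians were 0.871, 0.354 and 0.962 in the hb34 libraries.

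Of 14 cell wall expansion genes 3 fell and 1 rose with edgeR (3 and 2 when adjusted over the list alone; limma-voom called 3 lower and 0 higher). XTH31, a xyloglucan endotransglucosylase/hydrolase gene, had 134.0 ± 27.7 CPM in WT and 40.5 ± 6.81 CPM in hb34 (SD, n = 3 each; log2 fold change -1.73, SE 0.19, adjusted p = 0.0102). The expansin genes EXPA5 (-0.92) and EXPA10 (-0.76) fell as well and XTH19 (2.02) rose. The list's median was -0.43, its mean 0.046 and its camera adjusted p 0.233. Of 22 nuclear photosynthesis genes 2 rose and 2 fell (2 and 6 when adjusted over the list alone). The 2 that rose, LHCB2.1 (0.92, SE 0.129) and LHCB2.2 (0.80, SE 0.134), lie in the chromosome 2 segment, and the 2 that fell were LHCB3 (-0.45, SE 0.0925) and the plastocyanin gene PETE2 (-0.42, SE 0.089). The photosynthesis list was lower (median -0.24, camera adjusted p = 0.0328; adjusted p = 0.598 with an estimated correlation). Its camera adjusted p was 0.111 without WT replicate 2, 0.0524 without WT replicate 3, 0.0853 without hb34 replicate 1, 0.0592 without hb34 replicate 3 and 0.0999 without a filter on low counts. With fry its adjusted p was 0.203. Among 15 brassinosteroid and gibberellin genes RGA, which lies in the segment, and BES1 (0.46, SE 0.101) rose and 0 fell in all 3 tools (1 lower at an unadjusted p under 0.05 in edgeR), and the same number, 2, rose when adjusted over the list alone. The BES1 call was kept in 8 of 18 alternatives and lost without each library in turn. The camera adjusted p of the list was 0.73.

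In the iron homeostasis list the ferritin genes FER1 (163.6 ± 29.7 to 51.5 ± 9.37 CPM) and FER4 (53.7 ± 1.53 to 25.1 ± 1.14 CPM, SD, n = 3 each) fell, with log2 fold changes of -1.67 (SE 0.182, adjusted p = 0.0102) and -1.10 (SE 0.109, adjusted p = 0.00833). BTS, an E3 ligase gene that limits iron uptake, rose (1.72, SE 0.285, adjusted p = 0.0213). In all, 1 of 14 iron genes rose and 2 fell, and 4 and 3 did when adjusted over the list alone (camera adjusted p = 0.73). Of 10 clock genes PRR7 (0.91) and RVE1 (0.94) rose, 2 when adjusted over the list alone (camera adjusted p = 0.13; 0.0193 without hb34 replicate 2; with all libraries, adjusted p = 0.598 with an estimated correlation). HAI1 (1.17) and RD29A (0.95) rose among 14 abscisate and drought genes, 4 when adjusted over the list alone (camera adjusted p = 0.356). In the flavonoid list CHI (-0.70) and FLS1 (-1.39) fell among 7 genes, 3 when adjusted over the list alone (camera adjusted p = 0.2). Of 11 reference genes UBQ10 rose (0.81, SE 0.188, adjusted p = 0.0484), a call kept in 9 of 18 alternatives and lost without each of the 6 libraries in turn, and 1 rose when adjusted over the list alone. The reference list's median was -0.029, its mean 0.111 and its camera direction higher (adjusted p = 0.541). The lists without a call outside the jasmonate lists were touch and wound response, heat shock, auxin, cell cycle, phosphate starvation, senescence and root markers. They held 55 measured genes, of which 0 passed with edgeR and limma-voom (16 at an unadjusted p under 0.05 with edgeR) and 9 of 72 with DESeq2, 5 higher and 4 lower. When adjusted over the list alone, 1 senescence gene rose and 4 fell, 1 phosphate gene fell and 0 of the other 5 lists passed. Camera adjusted p were 0.356 for touch and wound, 0.312 for heat shock, 0.42 for auxin, 0.541 for the cell cycle, 0.462 for phosphate starvation, and 0.42 for senescence, whose median was -0.32, mean 0.61 and camera direction lower. Touch and wound medians were -0.961, 1.09 and 1.37 in hb34 replicates 1, 2 and 3, and without hb34 replicate 1 that list's camera adjusted p was 0.000115. With all libraries it had an adjusted p = 0.771 with an estimated correlation. In the senescence list the transcription factor gene NAP had 5.04, 163.2 and 24.1 CPM in hb34 and 3.24 ± 0.378 CPM in WT (SD, n = 3; edgeR adjusted p = 0.0681). Its log2 fold change was 4.30, and 2.17 without hb34 replicate 2 (adjusted p = 0.0447). Of 16 root markers 1, SHR (log2 fold change 0.12, adjusted p = 0.767), had enough counts to be tested, and of 8 seed storage markers 0.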

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

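The removal of the chromosome 2 segment and the homeodomain list without HB34 were chosen after the result was seen. HB34 kept its direction and its side of the threshold in all 18 alternatives that refit the genes (log2 fold change -6.33 to -5.69). Against 1122 genes (675 higher, 447 lower), DESeq2 called 2664 (1652 and 1012), an adjusted p under 0.01 left 28 (20 and 8), a fold of at least 2 left 494 (334 and 160), and removing the chromosome 2 segment left 709 (382 and 327). Leaving out 1 library gave 3 to 1356 genes, 1 to 853 higher and 2 to 503 lower: 3 without WT replicate 1, 4 without WT replicate 2, 769 (502 and 267) without WT replicate 3, 888 (653 and 235) without hb34 replicate 1, 1356 without hb34 replicate 2 and 389 (274 and 115) without hb34 replicate 3. Each of these fits lost 1 library, so fewer degrees of freedom do not account for the differences between them. Their cause was not tested. With the other scalings, filters, dispersions, limma-voom and nuclear genes only, between 1018 and 1265 genes passed, and 961 to 1122 of the 1122 were kept with the same direction.

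With the replicate number as a block 5 genes passed (2 higher, 3 lower), all 5 among the 1122. Same-numbered libraries did not deviate together (correlations of -0.097, -0.11 and -0.26), and WT replicate 1 and hb34 replicate 3 correlated best (0.17). Each deviation was taken from the mean of its group of 3, so these correlations constrain each other. They cannot decide whether same-numbered libraries were grown or processed together.

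Of the lists, 6 passed. With an estimated correlation 0 did, with fry 1 (17 with its test for change in either direction) and without a filter on low counts 2. With 1 library left out 3 to 8 did (3 without WT replicate 2 and without WT replicate 3), the cause not tested. The list that passed with fry was the homeodomain family (adjusted p = 0.0206), which includes HB34. The odds ratio for changed genes within 1 Mb of HB34, 0.89 and not past the threshold, was above 1 with library size only (1.01), upper quartile scaling (1.05), a window of 0.25 Mb (1.02) and the segment removed (1.43), and 0 to 1.38 with 1 library left out, the cause not tested; the replicate block and the fits without WT replicate 1 or 2 called too few genes for a ratio to carry weight. Values that changed sign without being past the threshold on either side, the cause not tested, were CYP94C1 (-0.92), JOX2 (-0.22) and SHR (-0.086) without hb34 replicate 2 and SHR (-0.011) without WT replicate 1; with 1 library left out their highest values were 2.97, 2.27 and 0.283. Lists that did so are given with the adjusted p and its range with 1 library left out: brassinosteroid and gibberellin without hb34 replicate 1 (0.931) and without the segment (0.888; 0.629 to 0.931), iron with fry (0.618), without hb34 replicate 1 (0.696) and without WT replicate 3 (0.876; 0.45 to 0.876), jasmonate catabolism without hb34 replicate 2 (0.488; 0.0689 to 0.671), salicylate without hb34 replicate 1 (0.654; 0.163 to 0.876), and touch and wound without hb34 replicate 3 (0.787; 0.000115 to 0.831). Of the 54 named genes past the threshold, 44 to 54 stayed past it with the planned scalings, filters, tools and dispersions. On counts simulated with 200 changed genes, 3.03% of changes of 1.5-fold were called. That share does not carry over to the data, where 1122 genes passed at a less strict p cutoff, BES1 with a log2 fold change of 0.46 among them. Small changes may still be missed.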

Other observations

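Some GDSL-like lipases, of a family of esterases that includes enzymes acting on cutin and other surface lipids, fell in hb34. The family test, chosen after the result was seen, grouped tested genes outside the chromosome 2 segment by their RefSeq product. Of 32 GDSL-like lipase genes 11 fell where 0.817 were expected (Fisher's exact test, one-sided, odds ratio 20.5, adjusted p = 9.59e-08 over 456 tests of 228 families), and it was the only family past the threshold. The test takes genes as independent, so genes that shift together can make its p too small. Its p does not measure the spread between libraries. With edgeR, DESeq2 and limma-voom 0 of the 32 rose (0 higher at an unadjusted p under 0.05 in edgeR), 29 had a negative log2 fold change, and 19 had all hb34 libraries below all WT libraries, as had 3135 of the 17655 tested genes outside the segment (chance separates 10% in either direction). AT5G45670 went from 5.93 ± 2.57 to 0.35 ± 0.0769 CPM (SD, n = 3 each), AT5G45950 from 62.4 ± 5.43 to 21.7 ± 6.26 CPM, and the abundant AT3G16370 from 655.5 ± 57.2 to 412.5 ± 40.0 CPM. The same number, 11, fell under each other scaling, filter, tool and dispersion tried, but 0 fell with the replicate number as a block. With 1 library left out, 0, 1 and 6 fell without WT replicates 1, 2 and 3, and 8, 12 and 4 without hb34 replicates 1, 2 and 3.

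Of 178 tested genes within 1 Mb of HB34 on chromosome 3, 7 rose and 3 fell (odds ratio 0.89, p = 0.876, Fisher's exact test, two-sided).

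The patterns below were found in these data, and the tests of them were chosen after the result was seen, except the splits of the libraries, the correction for GC content and length, the list test without hb34 replicate 2 and the sum over loci related to PRS3, which were set before their own results were seen. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 1122 genes, and the highest of the others gave 0; 10 splits cannot give a share under 0.1, and this holds for the lists too. For the list tests with a preset correlation 7 of the 10 splits, the real one included, gave at least 6 lists past the threshold, and the highest of the others gave 10. After that count was seen, a rule was added that leaves the list test without hb34 replicate 2 open where at least 5 of 10 splits give as many lists as the real one. By the rule written before the result, its adjusted p of 0.0195 argued against hb34 replicate 2 as the source.

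For the higher genes at the start of chromosome 2, the values argue against a bias with GC content or gene length as the whole cause: their median log2 fold change was 0.95 before and 0.901 after the trend with both was removed (218 genes, quartiles 0.741 and 1.08). Nor does the pattern rest on 1 library: the lowest hb34 library median was 0.896. An extra copy of the segment in the sampled hb34 plants stays open: 89.0% of its genes had a log2 fold change above 0.5, but the end of the segment was drawn from these same values, so this share does not decide it. A regional effect of the mutation on transcription stays open and untested, and read coverage of genomic DNA was not analysed here.

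Without hb34 replicate 2, 4 of the 19 jasmonate synthesis genes (LOX2, LOX3, LOX4 and OPCL1) passed edgeR's test, which argues against that library as the whole source of their higher values. For the list as a whole this stays open: without hb34 replicate 2 its median was 0.28 in place of 0.71 and its camera adjusted p 0.0195 (over all alternatives 0.0061 to 0.598, the highest with an estimated correlation), but 7 of the 10 splits, the real one included, gave at least 6 lists with this preset-correlation test. Handling at harvest could not be settled, since 6 of 11 touch and wound genes were lower in hb34 replicate 2 than in replicate 3 (exact two-sided sign test, p = 1), while both lay above hb34 replicate 1. Another time of day at harvest stays open as well: 3 of 4 clock genes were at an extreme in hb34 replicate 2, PRR9 (62.5 CPM) and LHY (708.7 CPM) as the lowest and TOC1 (15.0 CPM) as the highest of the 6 libraries, but not CCA1 (548.6 CPM), and as these genes were picked after their values were seen, the count decides nothing. An effect of the hb34 mutation that differs in size between samples is a biological alternative and was not tested. All hb34 libraries also share the higher genes at the start of chromosome 2 and the lack of PRS3 reads. An effect tied to those differences cannot be told apart here from an effect of HB34. That limit holds for every difference between hb34 and WT given here.

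PRS3 and its neighbor AT1G10690 (chromosome 1, 3549920 to 3550848) had 0 counts in the hb34 libraries, which sequencing depth does not account for, since 1494 counts of PRS3 were expected at the WT level. No rise was seen in related genes: the summed CPM of PRS2 and 3 related loci was 202 ± 1.7 in WT and 195 ± 12.1 in hb34 (SD, n = 3 each). The difference was -6.45 (SE 7.03), where a rise of at least 13.1 was needed if PRS3 reads were assigned to them. With 3 libraries per group and this spread, the sum argues against such reads as the cause but does not exclude it. A change in the DNA at this place stays open: of 3 tested genes with at least 1 CPM in WT and no read in hb34, 2 are adjacent among the tested genes (share of 100000 random placements 0.00036), but this adjacency is what drew attention to them and is no independent test. On the other side of PRS3, AT1G10710 had 2, 1 and 0 counts in WT and 20, 27 and 21 in hb34. Whether such a change belongs to the hb34 allele or to the background of the line stays open.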
